A study of Mus musculus with 2 samples.

How the data were processed

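DNase-seq of mouse embryonic hindbrain was done in 2 libraries, biological replicates 1 and 2 of 1 group, sequenced on HiSeq 2500 and NextSeq 500 instruments per the labels. Reads were aligned by the authors to the mouse genome build mm10, and each library has its own list of peaks and its own list of hotspots, called per replicate and not on pooled reads, per the text beside the files. The series title marks the record as superseded by a later one, which was not examined. The aligner, the peak caller, their versions and filters, and the read depth are not given in the sources used here. The deposited peaks carry a signal value, the peak height, a whole number between 1 and 150, and every peak is 150 bp wide. How the authors scaled the height is not given in the sources used here; no value passes 150, and no common scaling between the libraries is visible in the values, so heights were compared mainly by rank. The deposited hotspots carry the -log10 of a false discovery rate estimate, from 1.30 to 6, with stronger ones written as 100, and the deposited hotspot score is this value in steps of 10. Hotspots at the value 100 made up 36.4% of those of replicate 1 and 35.3% of those of replicate 2, and every analysed peak lay in a hotspot of its own library. As no depth is known, precision is given as 95% intervals that cover counting error alone: exact Clopper-Pearson intervals for counted shares, and normal approximations for standardised differences and, on the log scale, for odds ratios.

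Peaks on chromosomes 1 to 19, X and Y were analysed. Peaks on the mitochondrial chromosome and on scaffolds were left out, as were repeated entries at the same position (32 in replicate 1 and 60 in replicate 2). Coordinates were turned to 1-based positions, and none of the analysed peaks or hotspots passed the end of its chromosome in the GRCm38 patch p6 sequence. Peaks of both libraries that overlapped by at least 1 bp were merged into sites, and a site with a peak of each library was called shared. Random placement moved the other library's peaks to random positions on the same chromosomes, beyond the first 3 Mb, 100 times. Protein-coding starts came from the basic set of GENCODE M21, with 41218 starts of 21677 genes. A promoter site lay within 1 kb of a start, and a distal site was assigned to the nearest start if within 100 kb. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.

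Gene lists, motifs, tests, thresholds and the rule for named genes were fixed before the data were examined. The 23 lists held 432 entries, 431 of them measured, with 12 genes entered in 2 lists each. They were Hox paralog groups 1 to 4, 5 to 8 and 9 to 13, hindbrain segmentation, hindbrain and rhombic lip domain factors, midbrain and isthmus, forebrain, neural progenitors, neurons, mature glia, neural crest and peripheral glia, mesenchyme and meninges, endothelium and pericytes, erythroid cells, myeloid cells and microglia, skeletal muscle, heart, liver, surface epithelium, choroid plexus and roof plate, germ cells, housekeeping, and Sox, Notch and Wnt signalling targets. Named were the 3 genes of each list with the highest promoter peaks by mean rank, the first 2 in alphabetical order with no promoter peak in either library, every Hox gene, the 10 genes with the most distal shared sites, the 10 highest sites and the 10 highest sites of each library alone. Genes named outside this rule are given as such, and some that meet it are not reported here.

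For promoters, the number of list members with a shared promoter site was set against 10000 random lists of the same size, matched on deciles of the CpG observed to expected ratio in 1001 bp around the start. For distal sites, the mean number per gene was set against 10000 random lists matched on deciles of the length of the territory nearest to the gene. Both permutation tests were two-sided, with a smallest p of 0.0002, Benjamini-Hochberg adjustment over the 23 lists and a threshold of 0.05. Hox groups 1 to 4 and 9 to 13 were compared by a two-sided Fisher's exact test and a two-sided permutation test of height ranks (100000 permutations). For motifs, 33 consensus sequences were searched on both strands in the central 150 bp of each distal shared site and in windows 1 kb to each side, with an exact binomial test on sites with a match in only 1 of centre and upstream flank. Motifs of sites in 1 library alone were compared by two-sided Fisher's exact tests. Later tests used Mantel-Haenszel odds ratios over GC bins of 5 percentage points and shares standardised over peak height in bins of 10. Copies in the genome were counted from the central 31 bases of a site.

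Checked on simulated data, the promoter test gave a permutation p below 0.05 for 3% of 200 random lists, and called 90% of 100 lists set to an open rate of 95%. The simulated lists were drawn from all genes, so they do not check lists of neighbouring genes or lists whose matched random lists are mostly open. The distal test gave a permutation p below 0.05 for 1.5% of 200 random lists, and called 91% of 100 lists with tripled counts plus 1. Both called 0% of the random lists after adjustment. That value was nearly fixed in advance, as the simulation adjusted over 200 lists and used fewer random draws than the main tests. The motif test called 0.152% of motifs over 20 runs without signal, and recovered a CTCF consensus planted in 3% of centres at 3.03%. An overlap planted at 50% was recovered at 50%.

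Alternatives were a 50% reciprocal overlap, peaks above their library's median height, equal numbers of top peaks, hotspots in place of peaks, promoter windows of 500 bp and 2500 bp, a distal limit of 50 kb, no matching, the median in place of the mean, central windows of 300 bp, shuffled dinucleotides as background, and each library alone. Added after the data were seen were the removal of peaks inside hotspots of over 2 kb and matching on both CpG ratio and whether a gene has more than 1 start.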

Results

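DNase-seq marks open chromatin: the nuclease DNase I cuts accessible DNA in nuclei, and the cut ends are sequenced. The series holds 2 biological replicates of 1 group, hindbrain of mouse embryos of the strain B6NCrl at day 11.5, each from embryos of both sexes pooled together. The hindbrain is the part of the neural tube that forms the medulla, pons and cerebellum, and at this age it holds dividing progenitors beside newly formed neurons. Replicate 1 had 150613 deposited peaks and replicate 2 had 195264, of which 150176 and 194873 lay on the main chromosomes and were analysed. Peaks were called by the authors in each replicate separately. Each was 150 bp wide and carried a height of their making, a whole number of at most 150 in these files. Heights are given for replicate 1 and then replicate 2, and for a gene as its highest promoter peak in each. The median height was 36 in replicate 1 (quartiles 25 and 58) and 50 in replicate 2 (quartiles 36 and 79). Hotspots, the wider regions of raised cutting, covered 44.7 Mb in replicate 1 and 73.7 Mb in replicate 2, with a mean width of 342 bp and 478 bp. Read depth is unknown, as the files give no read counts. A group of 2 libraries permits no test across samples, so p-values describe sites and genes within these 2 libraries, and intervals cover counting error only.

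The first question was how far the replicates marked the same sites. The 10 strongest sites of both libraries by mean rank were all promoters. The strongest lay at Hjurp, which encodes a chaperone of the centromeric histone (chromosome 1, 88277536 to 88277705, mm10), with a height of 145 in replicate 1 and 149 in replicate 2. Next came the promoters of the histone deacetylase gene Hdac4 (132 and 146), the cohesin subunit gene Stag1 (131 and 148), Tbl2 (131 and 147) and the kinase gene Pim1 (133 and 145). The other 5 were Dcun1d4, the cholesterol synthesis gene Hmgcs1, the Integrator subunit gene Ints7, Ubald2 and the chloride channel gene Clic4, at heights from 131 to 139 in replicate 1 and of 144 or 145 in replicate 2.

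Of the replicate 1 peaks, 67.5% overlapped a replicate 2 peak by at least 1 bp (exact 95% interval 67.2% to 67.7%), against 2.34% after random placement. Of the replicate 2 peaks, 51.6% overlapped a replicate 1 peak (51.3% to 51.8%), against 1.81% after random placement. Overlap followed height: it was 24.9% among replicate 1 peaks of height 20 or less and 99.5% among those above 120, and 11.6% and 98.4% in replicate 2. The median height of overlapping peaks was 45 in replicate 1 and 73 in replicate 2, and that of the others 25 and 38. Merging both lists gave 231068 sites, of which 97657 (42.3%) held a peak of each library and are called shared here, while 45619 held only replicate 1 peaks and 87792 only replicate 2 peaks. With the lists brought to equal length the shares came to 62.8% and 62.0%.

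**Figure D1:**
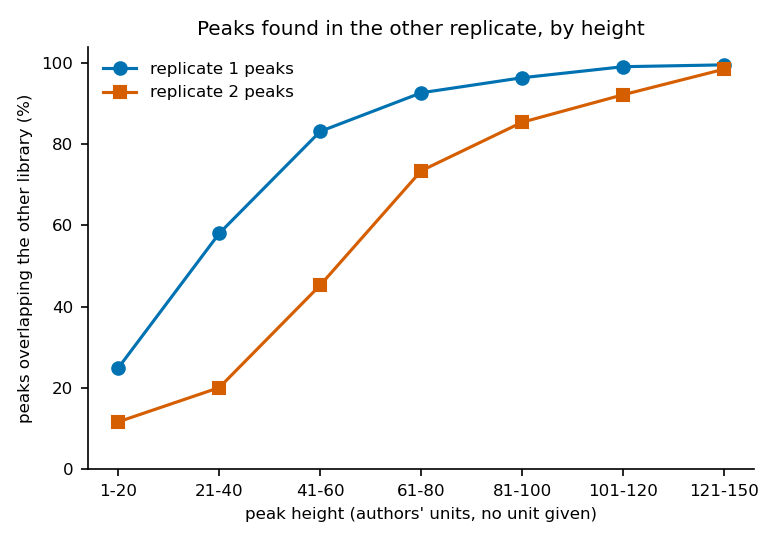
Percent of peaks of each library that overlapped a peak of the other library (vertical axis) by peak height in bins (horizontal axis), with replicate 1 and replicate 2 as separate lines. Both lines climb with height, from 24.9% to 99.5% in replicate 1 and from 11.6% to 98.4% in replicate 2.

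Sites open in both libraries were then compared by height. The 3 neural progenitor genes with the highest promoter peaks of their list had heights of 120 and 142 at Hes1, 121 and 140 at Hey1 and 122 and 138 at Hes5. All 3 encode repressors that act downstream of Notch. These heights lay above the libraries' upper quartiles of 58 and 79, but the genes were picked by height. Heights at named promoters of other lineages ranged widely: 129 and 144 at Foxa3, a liver factor gene, 120 and 139 at Ets1 and 99 and 130 at the germ cell gene Dazl, against 37 and 60 at Cd68, a macrophage lysosomal protein gene, 47 and 93 at Myod1, the muscle determination factor gene, and 25 and 63 at Trf, which encodes transferrin. Over the 91962 sites matched 1 to 1, Spearman's rho between the libraries was 0.843 and Pearson's r of log2 heights was 0.828. Promoter sites gave a rho of 0.930 (24943 sites) and distal sites 0.788 (67019 sites). Heights were greater in replicate 2 at 94.6% of matched sites, with a median ratio of 1.43 (quartiles 1.22 and 1.78). No common scaling of heights between the libraries is known, so the ratio cannot be read as stronger opening in replicate 2. These correlations run across sites, which are not independent replicates.

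Promoters, taken as DNA within 1 kb of a protein-coding start, held 26.9% of the shared sites (26.6% to 27.2%), against 2.36% of randomly placed sites. Another 3.46% lay in exons, 32.1% in introns and 37.5% between genes. Promoter shares were 25.2% of all replicate 1 peaks and 19.6% of all replicate 2 peaks. Among sites of 1 library alone they were 22.8% in replicate 1 and 12.4% in replicate 2, and the exact intervals of these shares did not overlap. A shared promoter site was present at 14298 of 21677 protein-coding genes (66.0%). Housekeeping genes were open throughout, with all 24 members of that list marked in both libraries, among them Vcp, an ATPase of protein turnover (124 and 140), the ribosomal protein gene Rpl13a (121 and 142) and the cytoplasmic actin gene Actb (128 and 138).

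Genes of neurons were open at their promoters more often than genes of like CpG content. Of 27 neuron genes, 26 had a shared promoter site, against a mean of 20.02 in random lists matched on promoter CpG content (permutation p = 0.0004, adjusted p = 0.00230 over 23 lists). The highest promoters of the list were those of the neuronal tubulin gene Tubb3 (112 and 140) and of the transcription factor genes Ebf3 (106 and 141) and Ebf2 (107 and 137). Mesenchyme and meninges genes were also open more often, 15 of 17 against 11.1 (permutation p = 0.0052, adjusted p = 0.0239), with heights of 88 and 131 at the growth factor receptor gene Pdgfra, 102 and 119 at Tbx18 and 98 and 117 at Foxc1. Postn, which encodes the matrix protein periostin, had no promoter peak in either library. In the opposite direction, only 1 of 18 germ cell genes was open against 8.38 in random lists (permutation p = 0.0002, the smallest the lists can give, adjusted p = 0.00153). That gene was Dazl, which encodes an RNA-binding protein of germ cells (99 and 130), while Acrv1 of the acrosome and the oocyte growth factor gene Gdf9 had no peak.

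All 3 Hox lists were open less often than their CpG content would give: 6 of 12 genes of paralog groups 1 to 4 against 9.72 (permutation p = 0.0102, adjusted p = 0.0391), 6 of 11 of groups 5 to 8 against 10.6 and 7 of 16 of groups 9 to 13 against 14.9 (permutation p = 0.0002 and adjusted p = 0.00153 for both). The random lists hold scattered genes, whereas Hox genes lie in clusters, share sites and are not independent, so these p-values overstate the evidence. In replicate 2 alone the Hox counts were 10 of 12, 9 of 11 and 13 of 16, and none of the 3 lists was called. Replicate 1 alone gave 7, 6 and 7, and groups 1 to 4 were not called. No Hox list was called without matching on CpG content, and other settings ended the call of groups 1 to 4 or 5 to 8 as well. Among peaks above their library's median height neither higher list was called (permutation, adjusted p = 0.0544 for neurons and 0.212 for mesenchyme), and mesenchyme was not called at 2500 bp or without CpG matching (permutation, adjusted p = 0.193 and 0.140). Without peaks inside hotspots of over 2 kb, a setting chosen after the data were seen, the differences from the random share turned to -0.105 and -0.109. That setting takes away the promoters inside wide hotspots by construction, and 18 of 27 neuron genes and 9 of 17 mesenchyme genes had a start in such a hotspot of replicate 2, against 4601 of all 21677 genes.

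The remaining 17 lists were not called. All 21 neural progenitor genes, 21 of 22 hindbrain segmentation genes, 26 of 27 genes of the Sox, Notch and Wnt signalling list, 36 of 39 hindbrain domain factor genes and 15 of 17 midbrain and isthmus genes were open, each close to the mean of their random lists. The ranges of those random lists reached 21, 22, 27, 38 and 17 open genes, so the test had almost no room for a higher call. Even 21 of 21 progenitor genes gave a permutation p of 0.185. These results therefore cannot show whether such promoters are open more often than others of like CpG content. Open members of these lists were the boundary ligand gene Efnb2 (116 and 144), the ventral homeobox gene Nkx6-1 (118 and 134), the dorsal homeobox gene Msx1 (113 and 129), the LIM homeobox gene Lhx2 (114 and 128) and the FGF target Etv5 (126 and 140). FGF antagonists of the midbrain and isthmus list followed, Spry2 (115 and 136) and Spry1 (98 and 131), with the nuclear receptor gene Nr4a2 (116 and 133). Dbx2, a homeobox gene of interneuron progenitors, had no promoter peak. Forebrain genes were open in 20 of 24 cases against 22.6 (permutation p = 0.0736, adjusted p = 0.242), with heights of 96 and 121 at the cortical gene Emx2, 85 and 121 at Dlx2 and 97 and 108 at the hypothalamic gene Sim1. With a window of 500 bp the forebrain share was called lower (0.75 against 0.930, permutation adjusted p = 0.0138). Without CpG matching the segmentation, domain factor, progenitor, signalling and housekeeping lists were called higher and the erythroid, myeloid, skeletal muscle and liver lists lower.

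Promoters of other cell types did not pass the test within 1 kb with all peaks. Choroid plexus and roof plate genes were open in 13 of 15 cases, led by Msx1, the ciliogenesis factor gene Foxj1 (107 and 131) and Otx2 (101 and 107), while the transthyretin gene Ttr had no promoter peak. Neural crest genes were open in 10 of 13 cases, with 120 and 139 at Ets1 and 98 and 122 at the melanocyte factor gene Mitf. Endothelium and pericyte genes were open in 12 of 18 cases, including the VEGF receptor gene Kdr (79 and 122), the pericyte potassium channel gene Kcnj8 (70 and 107) and Erg (59 and 108), and not the junction gene Cdh5 or Emcn. Of 16 surface epithelium genes 10 were open, with Grhl2 at 56 and 102, Epcam at 47 and 98, Grhl3 at 47 and 88 and no peak at the keratin genes Krt14 and Krt15. Among peaks above their library's median height the surface epithelium share was 0.188 against 0.627 and was called lower (permutation adjusted p = 0.00115). Of 12 mature glia genes 7 were open, including the glutamate transporter gene Slc1a2 (67 and 116) and the myelin genes Mbp (69 and 108) and Cnp (54 and 103), with none at Gfap or Mag.

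For blood, muscle, heart and liver genes the counts were 4 of 17 erythroid genes, 2 of 15 myeloid genes, 3 of 14 skeletal muscle genes, 7 of 16 heart genes and 3 of 20 liver genes, none of them past the test. With a promoter window of 500 bp liver genes were called lower (share 0.05 against 0.267, permutation adjusted p = 0.0381). With replicate 2 alone 12 heart genes (permutation p = 0.0108, adjusted p = 0.0621) and 7 skeletal muscle genes were open. Erythroid heights were 51 and 108 at Tal1 and 59 and 99 at the erythropoietin receptor gene Epor, with no peak at the haem synthesis gene Alas2 or at Gata1. Globin genes belong to a family with near-identical copies, so their state was treated as uncertain, though copies were not counted at their starts. Among myeloid genes Cd68 and the complement gene C1qa (28 and 43) were open and Aif1 and C1qb were not. Muscle heights were 53 and 85 at the troponin gene Tnnt1 and 50 and 59 at the titin gene Ttn beside Myod1, with none at the actin gene Acta1 or the acetylcholine receptor gene Chrna1. Heart factor genes had 88 and 124 at Tbx20, 69 and 108 at Gata6 and 62 and 108 at Gata4, and the contractile and calcium handling genes Myl7 and Pln had none. Liver heights were 129 and 144 at Foxa3, 79 and 96 at the apolipoprotein gene Apob and 25 and 63 at Trf, with none at Afp or Ahsg. A site within 1 kb of a start can also lie at the start of a neighbouring gene.

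**Figure D2:**
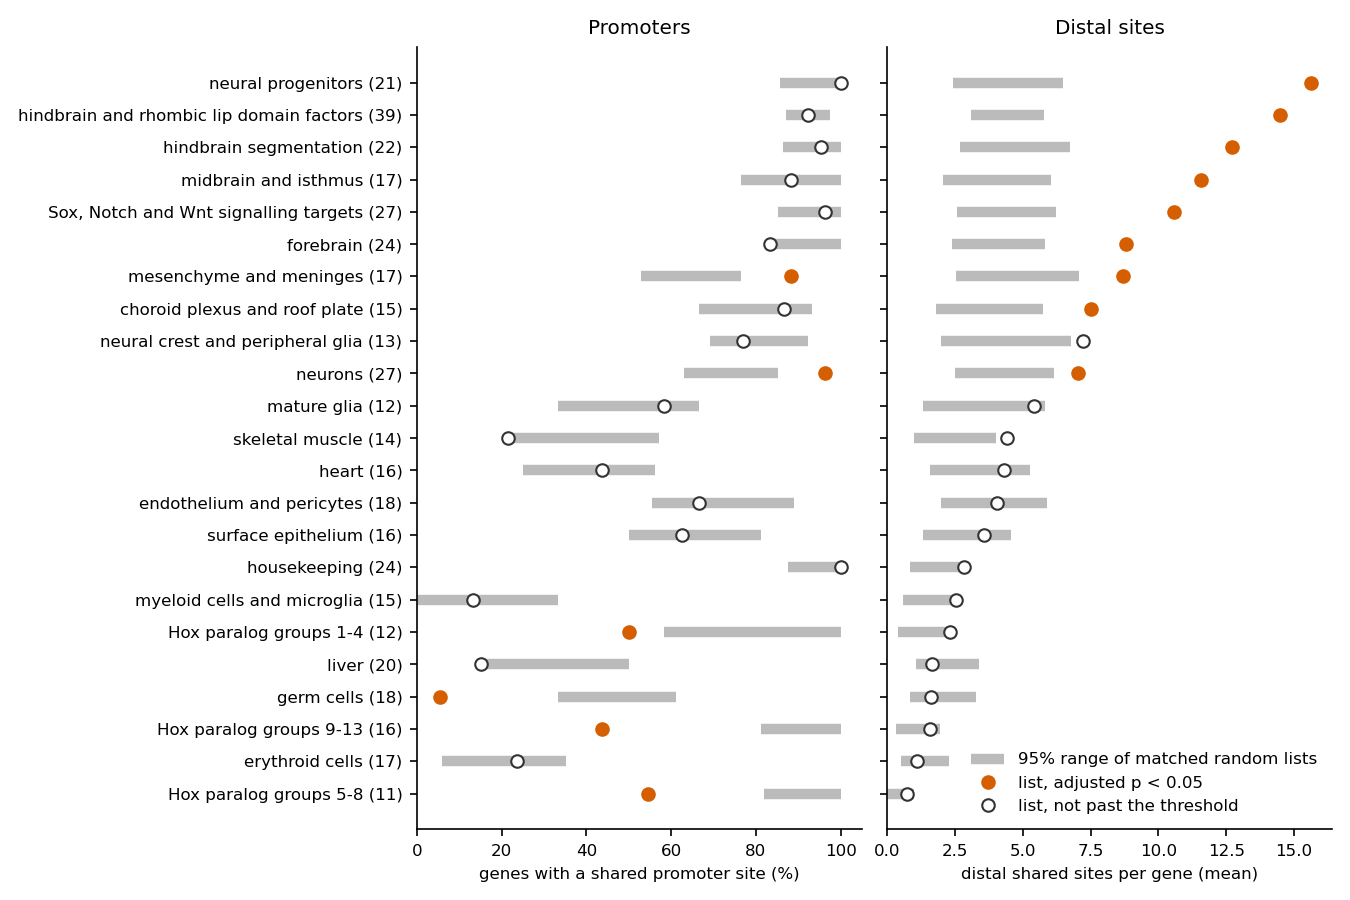
Gene lists (vertical axis) with the number of genes in brackets, by percent of members with a shared promoter site (left, horizontal axis in percent) and mean number of distal shared sites per gene (right, horizontal axis); grey bars are the 95% range of 10000 matched random lists and filled circles lists past the threshold. Neurons and mesenchyme lie above their promoter range and the Hox and germ cell lists below, and the 9 lists past the distal threshold had from 7.04 to 15.6 sites per gene.

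Distal sites, those over 1 kb from any protein-coding start, were counted at the nearest gene within 100 kb. The gene with the most was Sox2, a transcription factor gene of neural progenitors (chromosome 3, start at 34650405), with 55 shared distal sites, against a mean of 2.54 and a median of 1 per gene. Adamts18, which encodes a secreted protease, had 51, the neurodevelopmental gene Auts2 41, the ankyrin gene Ank3, Frmd4a and the progenitor gene Sox1 39 each, Zfp423, a zinc finger gene of cerebellar development, 38, and the corepressor gene Bcor and the forkhead gene Foxp1 37 each. Adamts18 also had 32 distal sites in replicate 1 only, at a median height of 9, against 26 over all sites of replicate 1 only. At Sox2 the median was 36.5 over 24 such sites. The heights of the shared distal sites were not compared between these genes. At the other end, 35.9% of genes had none.

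Of the 23 lists 9 had more distal shared sites than random lists matched on territory length, and 0 had fewer. Neural progenitor genes averaged 15.6 sites (SD 12.6 across 21 genes), 3.70 times the mean of random lists (4.22, range 2.43 to 6.48), with 19 at Hes1, 8 at Hey1 and 6 at Hes5. Hindbrain domain factor genes averaged 14.5 (SD 9.41 across 39 genes), 3.35 times random, with 26 at Msx1, 17 at Nkx6-1, 15 at Lhx2 and 10 at Dbx2. Midbrain and isthmus genes averaged 11.6 (3.04 times; Spry2 16, Spry1 13), hindbrain segmentation genes 12.7 (2.85 times; Efnb2 14), signalling genes 10.6 (2.52 times; Etv5 7) and forebrain genes 8.79 (2.23 times; Emx2 29, Sim1 16, Dlx2 11). All 6 had a permutation p of 0.0002, the smallest the lists can give, and an adjusted p of 0.000767. Choroid plexus and roof plate genes averaged 7.53 (2.16 times, permutation p = 0.0032, adjusted p = 0.0103; Otx2 31, Foxj1 5, Ttr 3), mesenchyme genes 8.71 (1.92 times, permutation p = 0.0036, adjusted p = 0.0103; Pdgfra 16, Tbx18 13, Foxc1 10, Postn 7) and neuron genes 7.04 (1.70 times, permutation p = 0.0068, adjusted p = 0.0174; Ebf2 21, Ebf3 14, Tubb3 6). Outside the called lists, neural crest genes averaged 7.23 and skeletal muscle genes 4.43 (permutation, adjusted p = 0.0531 for both, with calls under some settings), mature glia genes 5.42, heart genes 4.31, endothelium genes 4.06, surface epithelium genes 3.56, housekeeping genes 2.83, myeloid genes 2.53, liver genes 1.65, germ cell genes 1.61 and erythroid genes 1.12.

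The progenitor, domain factor, segmentation, midbrain and signalling lists passed under every setting tried. Neuron genes were not called with replicate 1 alone (9.48 against 6.25, permutation, adjusted p = 0.0718), and with replicate 2 alone 14 lists were called, the 3 Hox lists, heart and neural crest added. Skeletal muscle genes were called higher with a limit of 50 kb, with the median and without peaks in hotspots of over 2 kb (permutation, adjusted p = 0.0290, 0.0337 and 0.0475), and neural crest genes without matching on territory (0.00368). Without peaks inside hotspots of over 2 kb, a setting chosen after the data were seen, the forebrain, neuron, mesenchyme and choroid plexus lists were no longer called, forebrain genes averaging 3.88 against 3.52. That setting takes away sites in wide hotspots by construction. Such a hotspot of replicate 2 held a start of 21 of 24 forebrain genes, against 4601 of all 21677 genes. It also held a start of 35 of 39 domain factor genes, whose list stayed called. Against random lists of transcription factor genes, a comparison likewise added later, progenitor and domain factor genes lay above the range and the other 7 called lists inside it, among them segmentation (7.55 to 12.8), midbrain (6.06 to 11.8), signalling (7.78 to 12.5) and forebrain (6.67 to 11.4). The median in place of the mean ended the choroid plexus call, and restriction to peaks above the median height those of neurons and mesenchyme.

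Hox genes are expressed in nested domains along the hindbrain and spinal cord, and paralog groups 1 to 4 have their anterior limits in the hindbrain, so groups 1 to 4 were compared with groups 9 to 13. Shared promoter sites in groups 1 to 4 included those at Hoxa4 (74 and 130), Hoxd1 (63 and 115), Hoxb4 (57 and 106), Hoxc4 (40 and 92) and Hoxd3 (35 and 109). In groups 5 to 8 they were present at Hoxb5 (100 and 122), Hoxa7 (54 and 121), Hoxd8 (64 and 114), Hoxa5 (52 and 118), Hoxb8 (58 and 112) and Hoxc5 (47 and 90). Groups 9 to 13 had them at Hoxa10 (88 and 117), Hoxc13 (82 and 118), Hoxc10 (83 and 115), Hoxd10 (80 and 108), Hoxd9 (62 and 115), Hoxb13 (38 and 92) and Hoxa13 (25 and 105). These are heights of the highest promoter peak. The shared site itself was lower at Hoxb4 (102), Hoxc4 (78) and Hoxa13 (84) in replicate 2 and at Hoxc5 (40) in replicate 1. Peaks in replicate 2 alone marked Hoxa2 (116), Hoxb3 (104), Hoxb2 (102), Hoxb1 (90), Hoxb6 (100), Hoxc6 (87), Hoxb7 (84), Hoxd13 (116), Hoxd11 (104), Hoxa11 (100), Hoxa9 (97), Hoxb9 (97) and Hoxc12 (89), and a peak in replicate 1 alone marked Hoxd4 (36). Hoxa3, Hoxa6, Hoxc8, Hoxc9, Hoxc11 and Hoxd12 had none; the single annotated start of Hoxa3 lies at 52213115 on chromosome 6, between those of Hoxa6 and Hoxa7.

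Promoters of groups 1 to 4 and of groups 9 to 13 did not differ detectably in how many were open, with 6 of 12 against 7 of 16 (odds ratio 1.29, two-sided Fisher's exact p = 1). Ranks of their highest promoter heights did not differ detectably either, with two-sided permutation p = 0.832 in replicate 1 (median 35.5 against 0, a gene with no peak counting as 0) and p = 0.639 in replicate 2 (105 against 102). With a promoter window of 2500 bp the counts were 10 of 12 and 9 of 16 (odds ratio 3.89, exact p = 0.223), and without peaks in hotspots of over 2 kb 2 of 12 and 5 of 16 (odds ratio 0.440, exact p = 0.662), where the setting itself removes promoters, as 7 and 2 genes had a start in such a hotspot of replicate 2. Neighbouring Hox genes share sites and are not independent. The libraries differed over all 4 clusters. Hotspots covered 3.79% of the Hoxa cluster in replicate 1 and 34.5% in replicate 2 (chromosome 6, 52153317 to 52265879), with 21 and 102 peaks. They covered 2.95% and 32.4% of Hoxb (chromosome 11, 96189316 to 96370751; 26 and 142 peaks), 2.86% and 33.1% of Hoxc (chromosome 15, 102916103 to 103039394; 15 and 109 peaks), and 4.13% and 26.8% of Hoxd (chromosome 2, 74663310 to 74767979; 21 and 64 peaks). Distal shared sites averaged 2.33 per gene in groups 1 to 4, 0.727 in groups 5 to 8 and 1.56 in groups 9 to 13, with 13 at Hoxb13. With replicate 2 alone the means were 13.4, 4.82 and 13 against 2.34, 0.740 and 1.84 in random lists, and all 3 lists were called higher (permutation adjusted p = 0.000418 for each).

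**Figure D3:**
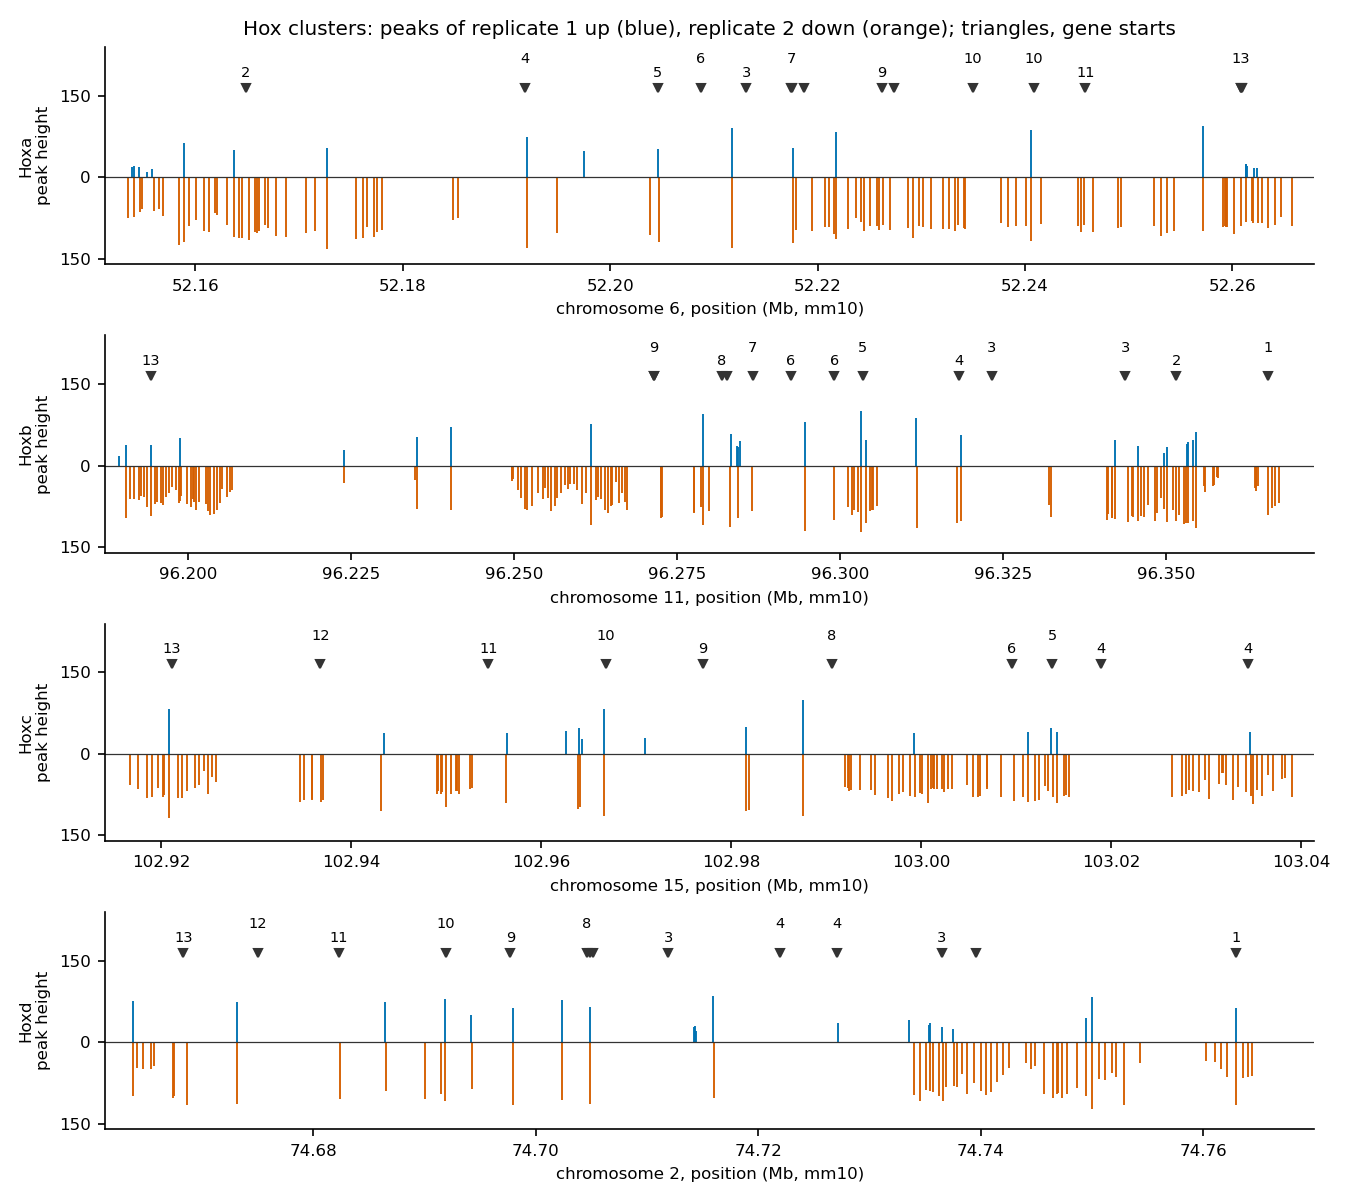
Peaks over the 4 Hox clusters, by position on the chromosome in Mb (mm10, horizontal axis) and peak height (vertical axis), with replicate 1 drawn upwards, replicate 2 downwards and annotated starts of Hox genes, 1 gene left out, as triangles with their paralog number. Replicate 2 had 102, 142, 109 and 64 peaks over Hoxa, Hoxb, Hoxc and Hoxd and replicate 1 had 21, 26, 15 and 21.

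Sequence motifs were counted in the central 150 bp of the 71390 distal shared sites and in windows 1 kb to each side. Of 33 consensus sequences 25 were more frequent in the centres and 3 less frequent. The consensus of the insulator protein CTCF was in 8.81% of centres and 0.142% of flanks, a ratio of 61.9, and that of RFX factors, which act in ciliated and neural cells, in 0.322% (ratio 41.8). These ratios were 32.1 and 20.1 with replicate 2 alone, and the RFX ratio was 24.9 with replicate 1 alone. Further high ratios were those of the NFI dimer (6.62), the SOX dimer (6.24), the single RFX site (4.57), the neuronal gene repressor REST (3.46), EBF (3.33), PBX with MEIS, cofactors of Hox proteins (3.33), ZIC (2.44), the E-box CAGCTG of proneural factors (2.20, in 16.0% of centres), SP and KLF factors (2.42) and GLI, the effector of hedgehog signalling (1.93). Matches to the NFI dimer and the SOX dimer were rare, each in 53 centres (0.0742%). The SOX consensus was in 24.3% of centres against 19.4% of flanks (ratio 1.254), the POU octamer had a ratio of 1.59 and the E-box CATCTG 1.41. By exact binomial tests on sites that differed between centre and flank, the adjusted p of each ratio named here as higher was at most 3.84e-05, that of GLI.

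Some consensus sequences of other lineages were not called against flanks: HNF4 of liver had a ratio of 0.982, MEF2 of muscle 0.743 and the myeloid factor SPI1 1.00, and the consensus of HNF1 was in 0 centres. With replicate 2 alone SPI1 was called higher (1.19) and MEF2 lower (0.719), and against shuffled sequence both were higher (1.34 and 1.74). The consensus joining PBX and HOX had a ratio of 0.997 (exact adjusted p = 0.567) among shared sites, and 1.69 with replicate 2 alone. The GATA consensus had a ratio of 0.619 and the homeodomain consensuses TAATTA and TAATKR 0.680 and 0.912, all 3 called lower. Against centres with shuffled dinucleotides in place of flanks, TAATTA had a ratio of 2.24 and TAATKR 1.32, both higher, NFY went from 1.47 to 0.816, and GATA, at 0.929, was not called. The same background gave 13.2 for the SOX dimer, 7.23 for SP and KLF, 6.22 for PBX with MEIS, 3.53 for NFI, 3.02 for the POU octamer, 1.52 for ZIC and 1.43 for CAGCTG. Centres of 300 bp lowered the ratios of CTCF to 29.4, RFX to 16.5, NFI to 4.19, the SOX dimer to 4.06, the single RFX site to 2.81, REST to 2.23 and EBF to 2.20. Calls of AP-1, ETS, GRHL, TCF-LEF, the retinoic acid DR5 element and the NR2F element DR1 were each lost in at least 1 setting.

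**Figure D4:**
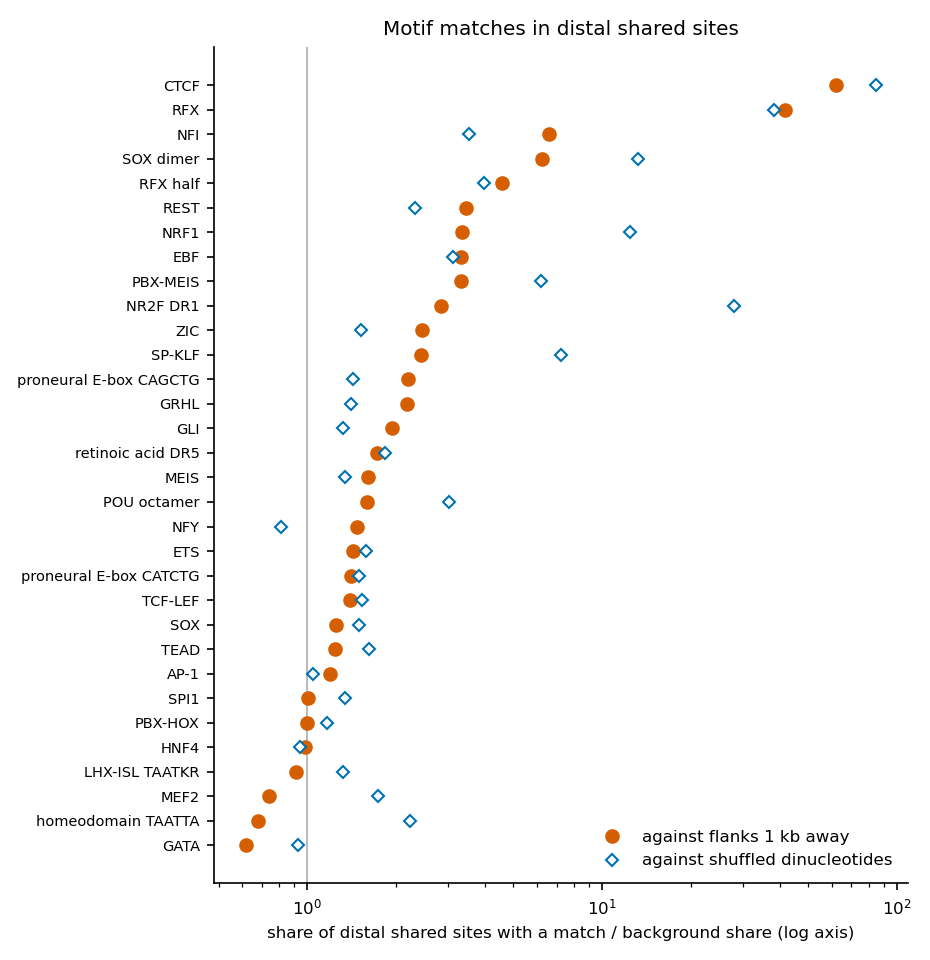
Ratio of the share of distal shared sites with a motif match in the centre to the share in flanks 1 kb away (horizontal axis, log scale), and the same ratio against shuffled centres, for each consensus with a match (vertical axis); circles are ratios to flanks and diamonds ratios to shuffled sequence. CTCF lies highest at 61.9 and GATA lowest at 0.619 against flanks, while TAATTA stands at 0.680 against flanks and 2.24 against shuffled sequence.

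Sites found in 1 library alone were compared last. The strongest of replicate 1 lay at the promoters of the corepressor gene Tle4 (129), the Wnt pathway gene Dact3 (128), Nmt2 (127), the disulfide isomerase gene P4hb (with 2 sites of heights 124 and 120), the centrin gene Cetn3, the acetyltransferase gene Kat6b and Iqcd (121 each), in an intron by Clec11a (119) and 15355 bp from Btg2 (116). Those of replicate 2 lay at the promoters of the GTPase gene Rab1a (145), the importin gene Kpna3 (142), Dact3 (142), P4hb, Cetn3 and the chromatin remodeller gene Ep400 (141 each), Sertad2, Pja2 and Crocc (140 each) and Kat6b (139). Dact3, P4hb, Cetn3 and Kat6b had such a site in each library, as neighbouring peaks that did not overlap. Replicate 1 sites above height 100 lay in a hotspot of the other library in all 67 cases (exact 95% interval 94.6% to 100%), and replicate 2 sites above 100 in 86.0% (83.9% to 87.9%). At height 40 or less the shares were 33.4% and 2.12%, and over all such sites 39.8% and 7.46%. A site counted as replicate 1 only can thus still lie in DNA of raised cutting in replicate 2, more often than the reverse. The same height limits were used in both libraries, though no common scaling is known.

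Replicate 2 had more distal sites of its own, in proportions that differed between lists. Over all genes there were 55795 distal sites in replicate 2 only and 25072 in replicate 1 only, a ratio of 2.23. The counts were 182 and 8 at Hox genes of groups 9 to 13 (ratio 22.8), 132 and 10 at groups 1 to 4 (13.2), 45 and 1 at groups 5 to 8, 272 and 35 at heart genes (7.77), 202 and 38 at neural crest genes (5.32), 506 and 101 at forebrain genes (5.01), 38 and 10 at germ cell genes (3.80), 917 and 254 at hindbrain domain factor genes (3.61) and 22 and 7 at erythroid genes (3.14). Signalling genes had 242 and 116 (2.09), progenitor genes 216 and 118 (1.83), housekeeping genes 43 and 30 (1.43) and surface epithelium genes 46 and 35 (1.31). Single genes with many replicate 2 sites, chosen after their values were seen, were the nuclear receptor gene Nr2f2 (76 against 10), Bcor (66 against 8), the T-box genes Tbx3 (68 against 2), Tbx15 (63 against 0) and Tbx5 (61 against 2), and Zdbf2 (61 against 0). Replicate 1 had 71 sites against 0 at Ric3, a chaperone gene of acetylcholine receptors, with a median height of 8, and 37 against 4 at Mid1 on the X chromosome, named likewise after their values were seen. Ratios between 2 libraries could not be tested against a spread between samples. With the peak lists brought to equal length, all sites of replicate 2 only numbered 54680, in place of 87792, and those of replicate 1 only 52156, in place of 45619, and the ratios by list were not computed at equal length.

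**Figure D5:**
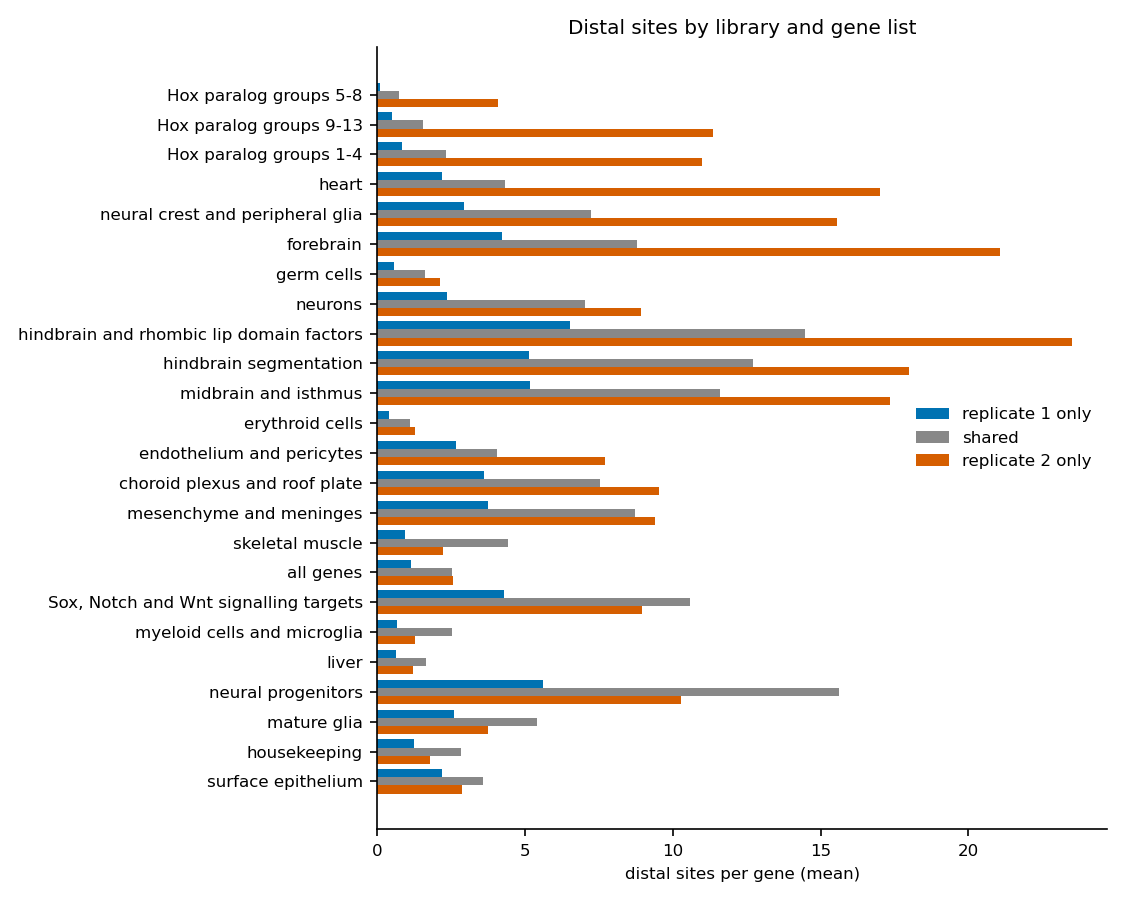
Mean number of distal sites per gene (horizontal axis, bars from 0) found in replicate 1 only, in both libraries and in replicate 2 only, by gene list (vertical axis), ordered by the ratio of replicate 2 only to replicate 1 only sites. The ratio was 45, 22.8 and 13.2 in the 3 Hox lists at the top and 7.77 at heart genes, against 2.23 over all genes.

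Motifs of the distal sites also separated the libraries. PBX with HOX matched 1.19% of sites in replicate 2 only and 0.426% of those in replicate 1 only (odds ratio 2.81, two-sided Fisher's exact p = 4.47e-39, adjusted p = 3.68e-38 over 33 motifs). The NFI dimer had an odds ratio of 6.08, the SOX dimer 2.68 (exact adjusted p = 0.0198), SP and KLF 1.78, REST 1.74, EBF 1.63, CAGCTG 1.32, MEIS 1.29 and CATCTG 1.28, all past the threshold. The dimers rested on few matches. NFI had 106 in replicate 2 only and 8 in replicate 1 only, and the SOX dimer 41 and 7. In the opposite direction, TCF-LEF matched 0.398% and 0.906% (odds ratio 0.437, exact p = 2.39e-24, adjusted p = 1.58e-23), and the POU octamer (0.646), the single RFX site (0.794), the single SOX site (0.813) and GATA (0.815) were also more frequent in sites of replicate 1 only. CTCF matches did not differ detectably (0.619% and 0.588%, odds ratio 1.05, exact adjusted p = 0.688). Sites are not replicates, and these tests compare 2 libraries.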

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

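No test was applied to the values below, which drew attention because they were counted outside the main chromosomes, in data that no comparison used, and lie above the limit that a count of 0 allows. That limit only separates the counts from 0 and does not make them unusual. The mitochondrial chromosome carried 31 peaks in replicate 1 (median height 150, range 123 to 150) and 29 in replicate 2 (median 124, range 103 to 145). Unplaced and unlocalised scaffolds carried 374 peaks in replicate 1 (median height 22) and 302 in replicate 2 (median 52). Replicate 2 thus had fewer peaks than replicate 1 in both places, against more on the main chromosomes (194873 and 150176), and its mitochondrial heights were the lower ones. With 1 library on each side these differences were not tested.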

How the results depend on the processing

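Chosen only after the data were seen were the removal of peaks inside hotspots of over 2 kb and the matching on both CpG ratio and number of starts. Of the 6 promoter calls, 36 of 54 alternative values kept direction and side of the threshold, and only germ cells did so throughout. Of the 9 distal calls 55 of 63 did, and of the 28 motif calls 156 of 168. Among lists and motifs not called, 18 of 153 promoter values, 9 of 98 distal values and 5 of 24 motif values passed under an alternative. Replicate 1 and 2 overlap shares were 58.4% and 44.8% with a 50% reciprocal overlap, 82.0% and 62.0% among peaks above the median height, 62.8% and 62.0% with equal list lengths and 78.0% and 52.8% with hotspots, and rho was 0.853 and 0.785 in the first 2 of these. The promoter share was 21.2% within 500 bp, 33.3% within 2500 bp, 36.0% above the median height and 19.998% to 25.5% with 1 library left out. The number of promoter lists called higher was 1 at 2500 bp, 6 without CpG matching, and 0 above the median height and without broad hotspots; the number called lower was 2 at 2500 bp, 9 without broad hotspots and 1 to 3 with 1 library left out. Promoter differences, observed minus random share, for calls that were lost: Hox groups 1 to 4 stood at -0.291 (500 bp), -0.000492 (2500 bp), -0.156 (no CpG matching), -0.155 (hotspots) and -0.238 to -0.0212 with 1 library left out. Groups 5 to 8 stood at -0.150 (2500 bp), -0.115 (no CpG matching), -0.196 (no broad hotspots) and -0.421 to -0.160 with 1 library left out, and groups 9 to 13 at -0.222 (no CpG matching) and -0.503 to -0.143. Neurons stood at 0.152 above the median height and reversed to -0.105 without broad hotspots, and mesenchyme at 0.194 (2500 bp), 0.223 (no CpG matching) and 0.156 (above the median height), reversing to -0.109 without broad hotspots. Removing broad hotspots takes away every promoter peak inside them, and 18 of 27 neuron genes and 9 of 17 mesenchyme genes had a start in one of replicate 2, against 4601 of all 21677 genes, so the filter itself lowers these lists more than random ones. From 8 to 14 distal lists were called higher with 1 library left out. Distal differences in sites per gene for calls that were lost were 0.352 for forebrain without broad hotspots; for neurons 1.60 above the median height, 1.26 without broad hotspots and 3.23 to 7.42 with 1 library left out; for mesenchyme 1.45 and 1.57 above the median height and without broad hotspots; and for choroid plexus 2.76 with the median and 1.54 without broad hotspots. Against shuffled sequence 1 motif was called lower, and the ratios of TAATTA (2.24), TAATKR (1.32) and NFY (0.816) reversed. Equal list lengths left 54680 sites of replicate 2 only. For the other changes the cause was not tested. Read depth is unknown, so its part in these differences cannot be given.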

Other observations

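Chosen only after the results were seen were the tests against transcription factor family genes and of displaced summits. The removal of peaks in hotspots of over 2 kb was a setting chosen after the data were seen and written down before its outcome, and the other tests were written down first. Replicate 2 had 296 hotspots of over 5 kb and replicate 1 had 11. The widest covered 20116 bp at the cortical gene Emx2 (chromosome 19, 59450569 to 59470684), and others lay at the floor plate gene Foxa2 (15700 bp), Dmrta2 (15158 bp), the GATA factor genes Gata3 (14333 bp) and Gata2 (13218 bp), Tnrc18 (13542 bp), Tbr1 of cortical neurons (13431 bp), Foxf1 (13245 bp), Nkx6-1 (12648 bp) and the dorsal interneuron gene Lbx1 (12366 bp), all named after their values were seen. Of these, replicate 1 hotspots covered 94.5% at Tnrc18, 62.1% at Emx2, 47.4% at Nkx6-1, 44.2% at Tbr1, 27.5% at Foxa2, 10.2% at Gata3, 3.22% at Dmrta2, 2.78% at Gata2, 2.17% at Foxf1 and 2.12% at Lbx1, and over all 296 a median of 46.9%. Starts of 235 genes lay inside them, 116 of which (49.4%) were in the lists or in 213 further genes of transcription factor families, against 2.92% of all genes. By list the counts were 17 of 24 forebrain genes, 23 of 39 hindbrain domain factor genes, 6 of 16 heart genes, 6 of 22 segmentation genes and 4 of 21 progenitor genes, and 0 for mature glia, myeloid, skeletal muscle, liver, germ cell and housekeeping genes.

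In numbers of distal shared sites, set against random lists drawn from the 213 family genes outside the lists and matched on territory, progenitor genes still averaged more (15.6 against 9.53, permutation p = 0.0002, the smallest the lists can give, adjusted p = 0.0008 over 20 lists). Forebrain genes did not differ detectably (8.79 against 8.95, permutation adjusted p = 0.931), nor did segmentation genes (12.7 against 10.1) or midbrain genes (11.6 against 8.81; permutation adjusted p = 0.127 for both). The same held for the other called lists, signalling (10.6 against 10.1, permutation adjusted p = 0.781), choroid plexus (7.53 against 8.06, 0.816), mesenchyme (8.71 against 9.48, 0.759) and neuron genes (7.04 against 9.18, 0.127). Lower than these random lists were erythroid (1.12 against 3.83), liver (1.65 against 4.97), germ cell (1.61 against 5.17) and endothelium genes (4.06 against 8.06), with a permutation adjusted p of at most 0.00333. These lists also hold genes that are not transcription factors. Against genes of all kinds matched on territory none of them was called, with random means of 1.26, 2.05, 1.86 and 3.68. The lower counts are thus relative to transcription factor genes and are no depletion against genes at large.

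The hotspots of over 5 kb in replicate 2 were weighed first. Whether these hotspots favour any kind of gene was not tested. If height tracked cutting alike in all regions, lower depth in replicate 1 would lose peaks of equal height alike. Replicate 2 peaks inside hotspots of over 5 kb overlapped a replicate 1 peak in 48.3% of cases. Outside them 80.5% did at equal height, a difference of -32.2 points (95% interval -33.7 to -30.8, 3731 peaks). Matching on GC content as well left -32.2 points (-33.6 to -30.7). The regions were chosen for their width in replicate 2, and promoter and distal peaks were not matched. As the scaling of height is also unknown, these values cannot exclude lower depth. Displaced summits would place the unmatched peaks in replicate 1 hotspots, but 15.1% (13.6% to 16.8%) of the 1930 unmatched peaks lay in one. Read depth, how the caller sets hotspot width, nuclease digestion, library preparation, the sequencing instrument and a difference between the embryo pools stay open. Instruments of 2 kinds were used, and how they were divided between the replicates is not stated here. No biological explanation was tested, as the design gives 1 group.

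The motif contrast between sites of 1 library alone was weighed next. At equal GC content the odds ratio of replicate 2 only against replicate 1 only sites was 3.43 for PBX with HOX (2.86 to 4.12) and 0.474 for TCF-LEF (0.403 to 0.558), so GC content alone does not account for the contrast of these 2 motifs. The other motifs were not compared at equal GC content. Among sites above the median height of their class the odds ratios were 4.09 (3.07 to 5.46) and 0.296 (0.234 to 0.376). The contrast of these motifs was thus not confined to the weaker sites of each class. Over all sites of 1 library only, the median heights were 26 in replicate 1 and 39 in replicate 2. As these lie below the library medians of 36 and 50, sites above them can still be weak, and weak sites are not excluded as a source. The contrast may reflect pools that differed in cell composition or in the extent of tissue taken, a hypothesis that was not tested. These 2 libraries cannot separate it from library preparation or the sequencing instrument.

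The third pattern was the number of distal shared sites at hindbrain domain factor genes. It exceeded that of family genes in general by 4.74 sites per gene (14.5 against 9.75, range of random lists 8.08 to 11.5, permutation p = 0.0002, the smallest they can give). Without peaks in hotspots of over 2 kb the list still exceeded its matched random lists by 3.67 (7.56 against 3.90, range 2.82 to 5.15, permutation p = 0.0002). Neither membership of these families nor wide hotspots, each taken alone, therefore accounts for all of it. Whether both together do was not tested. A larger share of regulatory sites at genes active in this tissue is a candidate explanation. Expression was not measured here, so that link stays open.

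Some genes had many sites in replicate 1 only. Ric3 had 71 (chromosome 7, 109070356 to 109116905) with a median height of 8, and in 0 of them did the central 31 bases occur more than once in the genome. The share with more than 1 copy was 90.9% of 22 sites at Gm21887, 59.5% of 37 at Mid1 and 46.4% of 28 at Zfp987, and 0 at 14 of the 20 genes with the most such sites, against 2.54% of all distal sites of replicate 1 only and 1.90% of those of replicate 2 only. Low median heights like that of Ric3 were also found at Gm15446 (5), Usp40 (7), Zfp987 (8) and Adamts18 (9), and the others of the 20 had 14.5 or more. At Adamts18, 12.5% of 32 sites had more than 1 copy. Apart from Adamts18, these genes were named after their values were seen.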
